A study of Mus musculus with 4 samples.

How the data were processed

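Pachytene spermatocytes of adult mice were represented by 2 wild-type and 2 heterozygous Tcfl5 libraries. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads, fragmented and reverse transcribed from random hexamers, and the libraries were sequenced on a BGISEQ-500 as single-end reads of 50 bases. The protocol names no step that keeps the strand, so reads of overlapping genes on opposite strands may not be told apart. The deposited values are FPKM per gene, written with 2 decimals, per the file headers. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the mouse build GRCm38 (mm10), and the role of each tool is not given in the sources used here. No count was available here for these values, and the depth of each library is unknown. A value of FPKM divides by transcript length and by the mapped fragments of the library, so a rise in abundant transcripts lowers the value of every other gene, and the reads behind a value cannot be recovered at 2 decimals. The values summed to 473346, 468130, 492203 and 483954 FPKM in wild-type replicates 1 and 2 and heterozygote replicates 1 and 2.

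The files were joined by Entrez gene identifier. Symbols that a spreadsheet had turned into dates (27 genes) were restored by that identifier, of which 99.3% were found in the RefSeq gene table of GRCm38. In each file 1 row held no gene and was left out, and 1593 genes without a value in all 4 libraries were left out. A gene listed in some libraries only was set to 0 in the others, which applied to 1163, 1430, 1085 and 1491 genes in the order given above. The median of the highest value such genes had elsewhere was 0.06 to 0.07 FPKM. The joined table held 19445 genes, of which 16878 had a value in all 4 libraries. Coordinates are those in the deposited files, on GRCm38. For 533 genes the files give positions on scaffolds other than the primary chromosomes, and these are not printed. Transcript GC content came from the longest GENCODE transcript of each gene on GRCm38 and was available for 97.4% of tested genes. No mitochondrially encoded gene was listed.

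The test planned before the data were examined was a count model with, for FPKM, a fallback that became the main test. This was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) for the 13333 genes with a mean of at least 0.5 FPKM, with genotype as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values, and the ratios printed are ratios of mean FPKM. Gene lists fixed before the data were examined, 26 in number, and the X-linked and Y-linked genes were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, with an adjustment over the 26 sets tested. The chromosome was known for 99.9% of tested genes. Members were also counted by the gene test, adjusted over all genes and over the list alone. Camera with an estimated correlation and fry were run as alternatives. The planned rule for naming genes took Tcfl5, the 12 genes with the largest change in each direction among those passing, with both heterozygote libraries on the same side of both wild-type libraries and a mean of at least 5 FPKM in a genotype (planned as CPM), without uncharacterised or predicted symbols, and up to 4 members of each list with the smallest p. Since no gene passed, the rule's provision for that case applied, and the 12 genes of smallest p in each direction under the same conditions were named as not passing. A gene that the rule would name among the list members is not reported here.

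With 2 libraries per genotype there are 3 ways to split the libraries into groups of 2. The log2 values of the libraries correlated across genes at 0.983 to 0.991, and wild-type replicate 1 was closer to heterozygote replicate 1 (0.991) than to wild-type replicate 2 (0.990). Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, other thresholds, the replicate number as a block, leaving out each library, and the other set tests. Alternatives added after the first fit had called 0 genes were scaling to an equal sum, to median ratios and to the upper quartile, quantile normalization, a filter of at least 1 FPKM in at least 2 libraries, robust and trend-free limma, the spermatid or Sertoli marker mean as a covariate, corrections for a smooth trend on GC content or transcript length, and X-linked genes without uncharacterised symbols. The count of genes at least 2-fold apart in every library pair was added then too. The test was checked on simulated values with the spread fitted to the real libraries. In 10 draws of 13333 genes, 100 genes were changed by each size. The test called 31 to 47 of those changed by 1 log2 unit and 78 to 94 of those changed by 2. It made 2 to 13 false calls there, and at most 1 call in draws with no changed genes. The calls were not broken down by level, so these shares may not hold for genes with low values. The simulated spread had no part shared by replicate number. In the real data, deviations of same-numbered libraries from their genotype means correlated at 0.529 across genes. A gene list shifted by 0.5 log2 units was recovered by camera with 0 other lists called, on simulated values without correlation between genes. Tables were joined and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.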

Results

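The data are gene expression levels of pachytene spermatocytes, the male germ cells in the long prophase stage of the first meiotic division, isolated from the testes of adult C57BL/6 mice. Tcfl5 encodes a basic helix-loop-helix transcription factor of male germ cells. Cells with 2 intact copies of Tcfl5 (wild type, 2 libraries) were compared with cells carrying 1 disrupted copy (heterozygote, 2 libraries), and the comparison asks how a reduced dose of the gene alters the transcriptome of these cells. Polyadenylated RNA was sequenced as single-end reads of 50 bases, and the values are FPKM, which scales the reads of a gene by the length of its transcripts and by the mapped fragments of the library. A value was listed for 18282 and 18015 genes in wild-type replicates 1 and 2 and for 18360 and 17954 genes in heterozygote replicates 1 and 2. Total read counts were not given with the FPKM values, so the depth of each library is unknown in absolute terms. In all 4 libraries the commonest low value of single-transcript genes of just over 900 bases was 0.06 FPKM, which is what a single read would be worth if the libraries had similar depth. The most abundant transcripts were those of Ubb, a ubiquitin gene, at 3823 and 3796 FPKM in replicate 1 of the wild type and of the heterozygote, and of Ldhc, the lactate dehydrogenase of germ cells, at 3858 FPKM in replicate 2 of each. The 10 most abundant genes held 4.68% to 5.15% of the summed FPKM. Nothing states that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

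Tcfl5 itself, on chromosome 2 from 180621956 to 180642702 of GRCm38 on the minus strand, was lower in both heterozygote libraries than in either wild-type library. Its level was 248.7 and 237.7 FPKM in the wild type and 137.0 and 188.5 FPKM in the heterozygote. The group means were 243.2 ± 7.74 and 162.8 ± 36.4 FPKM (SD, n = 2 each), a 1.49-fold difference. The log2 difference on the log2(FPKM + 1) scale was -0.59 with a standard error of 0.16. With genotype as the only term, the difference did not pass the limma-trend test after Benjamini-Hochberg adjustment (adjusted p = 0.242). The values cover the whole gene, and which part of it the disrupted copy lacks is not given in the sources used here.

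The named genes are those with the smallest p in each direction. Of the 12 named genes higher in the heterozygote, the homeobox gene Hoxa4 was at 131.0 ± 5.62 FPKM against 43.5 ± 10.01 in the wild type, a 3.01-fold difference. Shf, which encodes an SH2-domain adaptor, was at 45.7 ± 2.96 against 12.4 ± 0.679 FPKM, a 3.67-fold difference. The LIM-domain genes Csrp2, Lims2 and Limd2 were 2.58-fold, 2.58-fold and 1.59-fold higher, and Limd2 was abundant, at 903.5 ± 9.09 against 569.3 ± 32.5 FPKM. Apip, an enzyme of the methionine salvage pathway, was 2.62-fold higher, Chrne, a subunit of the muscle acetylcholine receptor, 2.35-fold, Fam20a, a pseudokinase of the secretory pathway, 2.33-fold, the ciliary gene Fam161a 2.16-fold, the chloride channel gene Clic4 1.98-fold and Ttc1 1.70-fold. For Apip and Chrne the files give positions on scaffolds other than the primary chromosomes. Whether that placement affects their values was not tested. The beta-defensin gene Defb33 had the largest ratio among these, 6.34-fold, from 1.48 ± 0.311 to 9.39 ± 1.75 FPKM (SD, n = 2 for each of these groups).

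Among the 12 named genes lower in the heterozygote were Art1 and Art5, neighbouring genes for ADP-ribosyltransferases on chromosome 7 of GRCm38. Art1 (102101726 to 102111156) was at 1.24 ± 0.0849 FPKM in the heterozygote and 10.3 ± 0.679 in the wild type, 8.32-fold apart, and Art5 (102096879 to 102100307) at 22.9 ± 2.10 and 66.1 ± 8.58 FPKM, 2.88-fold apart. Ncs1, a neuronal calcium sensor, was 12.8-fold lower, from 6.03 ± 0.750 to 0.470 ± 0.170 FPKM. Bcl7c, a subunit of SWI/SNF chromatin remodelling complexes, was 3.85-fold lower, from 49.3 ± 3.49 to 12.8 ± 2.91 FPKM. Prkag2, the regulatory gamma subunit of AMP-activated kinase, was at 45.5 ± 3.04 against 104.5 ± 10.9 FPKM, 2.30-fold lower. The growth factor gene Pdgfa was 3.82-fold lower, the adaptor genes Sh2d7 and Dok7 6.16-fold and 5.55-fold, the small heat shock gene Hspb7 2.93-fold, the testis serine protease gene Prss40 2.86-fold, Dhrs4, a short-chain dehydrogenase, 2.72-fold and Cmtm1 2.40-fold (SD, n = 2 for each of these groups).

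**Figure D1:**
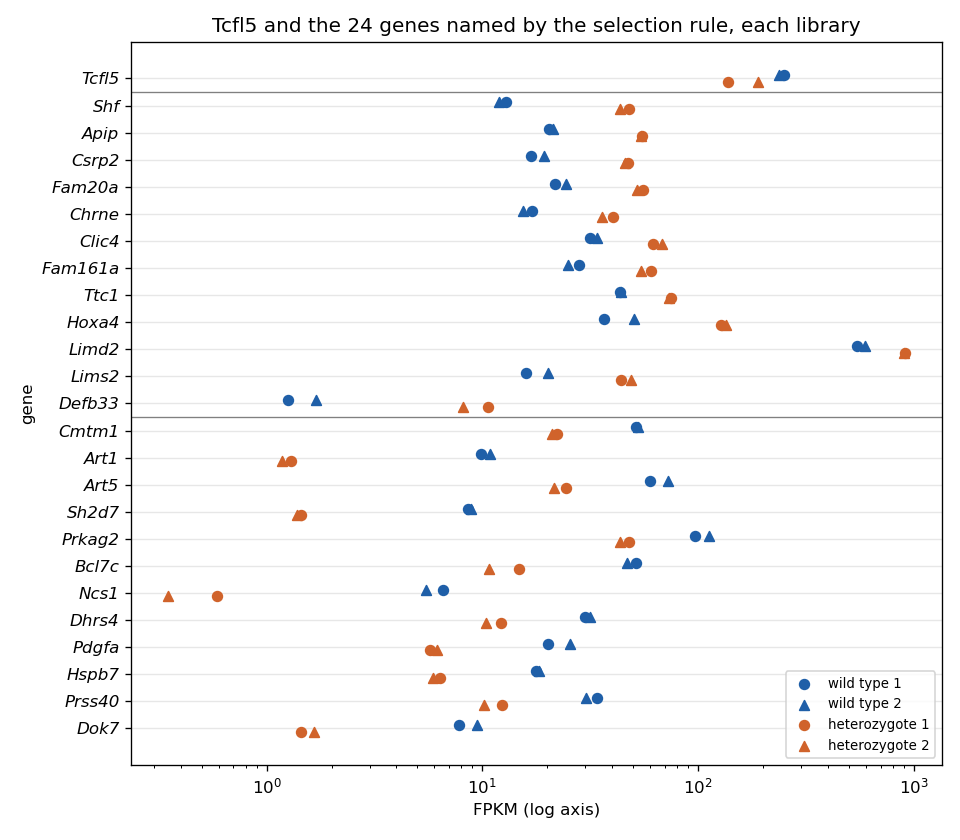
FPKM of Tcfl5, of the 12 named genes higher in the heterozygote and of the 12 lower ones, on a log axis, with 1 point per library (blue, wild type; orange, heterozygote; circles, replicate 1; triangles, replicate 2). For each gene both heterozygote libraries lie on the same side of both wild-type libraries, and Tcfl5 lies at 137.0 and 188.5 FPKM in the heterozygote against 248.7 and 237.7 FPKM in the wild type.

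None of these 24 genes passed the threshold in the main fit. With genotype as the only term, limma-trend called 0 of 13333 genes after Benjamini-Hochberg adjustment. The adjusted p of the 24 ran from 0.116 to 0.1195, and 0.116 was the smallest of any gene. At an unadjusted p under 0.05 there were 1759 genes, 1017 higher and 742 lower in the heterozygote, a balance that turned to 718 higher and 915 lower with scaling to an equal sum, to 706 and 759 with scaling to the upper quartile, to 562 and 716 without heterozygote replicate 1 and to 1219 and 1865 with the spermatid covariate. The count was 1113 with median-ratio scaling and 877 without heterozygote replicate 2. Among settings added after the data were seen, median-ratio scaling called 65 genes (18 rising, 47 falling; 21 of the 24 named), quantile normalization 119 (35 and 84; all 24 named), correction for GC content 57, correction for transcript length 63, and the spermatid and Sertoli marker covariates 382 and 54, while scaling to an equal sum or to the upper quartile called 0.

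A count of genes with a wide gap, added after the data were seen, gave 85 genes that were at least 2-fold apart on the FPKM + 1 scale in every pairing of a heterozygote with a wild-type library. Of these, 23 were higher and 62 lower in the heterozygote, and 3 and 7 of them had uncharacterised or predicted symbols. With a pseudocount of 0.1 there were 195 (57 higher, 138 lower). Without 1 library, where fewer pairs must differ, there were 190 without wild-type replicate 1 (99 higher, 91 lower), 141 without wild-type replicate 2 (40 and 101) and 160 without heterozygote replicate 1 (36 and 124). The excess of lower genes was thus absent without wild-type replicate 1. The higher set held the transcription factor genes Runx3 (11.0 ± 0.665 against 3.07 ± 0.438 FPKM) and Pou2f2 (17.5 ± 2.51 against 6.24 ± 1.41 FPKM). Runx3, like Apip and Chrne, has its position in the files on a scaffold other than the primary chromosomes. The lower set held the receptor gene Ngfr (2.28 ± 0.658 against 12.3 ± 0.877 FPKM), the flagellar gene Nme8 (27.8 ± 5.18 against 72.2 ± 3.62 FPKM), the kinase genes Akt1 (3.27 ± 0.841 against 9.92 ± 1.04 FPKM) and Limk1 (1.64 ± 0.226 against 9.24 ± 1.82 FPKM), and the transcription factor gene Sox17 (2.94 ± 0.516 against 8.96 ± 0.0212 FPKM; SD, n = 2 each). These 7 genes were chosen for naming after their values were seen. The multicopy Y-linked gene Sly, listed in the heterozygote alone at 4.35 and 3.48 FPKM, and the predicted gene Gm2977 belong to families with near-identical copies, and their values are uncertain. So are those of the predicted Y-linked genes Gm20931, Gm20827, LOC108168618 and LOC108168619 of the lower set, which were above 0 in the wild type alone. The last 2 have the same position and the same values, so 1 locus makes up 2 of the 62. With any gap at all, 42.6% of genes had both heterozygote libraries on 1 side of both wild-type libraries, where chance gives 33.3%. The split of the libraries by replicate number gave 41.3% and the remaining split 15.4%, so a share of this size was not particular to the genotypes. Barring ties, each gene falls in exactly 1 of the 3 splits. The 3 shares therefore depend on each other, and their average is fixed near 33.3% in any data.

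Genes for cytoplasmic ribosomal proteins were higher in the heterozygote as a group. Of 82 measured, 76 had a positive log2 difference, 63 were higher in both heterozygote libraries than in both wild-type libraries, and the median log2 difference was 0.30. Adjusted over the list alone, 37 rose and 0 fell (limma-trend), and over all genes 0 passed. Rps15 was at 599.2 ± 5.30 FPKM against 362.8 ± 39.6, Rpl9 at 375.3 ± 2.69 against 276.1 ± 0.792 and Rps13 at 496.8 ± 13.9 against 374.9 ± 0.0354 (SD, n = 2 each). Many of these genes have processed pseudogenes, between which reads can be split. The nuclear genes of oxidative phosphorylation showed a smaller difference of the same sign. Their median log2 difference was 0.16, 59 of 82 were higher in both heterozygote libraries, and 0 passed singly. The complex I genes Ndufb9 (225.2 ± 16.2 against 156.2 ± 3.30 FPKM) and Ndufa10 (40.6 ± 2.14 against 25.4 ± 3.67 FPKM) were among those with the smallest p. Both lists passed camera with a preset correlation of 0.01 (adjusted p = 7.9e-15 and 4.23e-06) and neither did with an estimated correlation (adjusted p = 0.990 each). Every set tested had that adjusted value, and the unadjusted p from camera with an estimated correlation was 0.222 and 0.0932. The oxidative phosphorylation call by camera was also lost after correction for transcript length (adjusted p = 0.0949), where its median log2 difference was 0.08. The ribosomal protein median was 0.21 after that correction, and that list stayed called.

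Among 46 measured transcription factors and transcriptional regulators of male germ cells, which include Tcfl5 itself, 35 had a lower mean log2 level in the heterozygote, with a median log2 difference of -0.15. Over the settings run the median went from -0.36 without wild-type replicate 2 to -0.007 without wild-type replicate 1. Tbpl1, a TBP-related factor needed in spermatids, was at 122.4 ± 9.60 against 174.6 ± 13.7 FPKM, Dmrtb1 at 564.8 ± 84.8 against 751.2 ± 55.7 and the X-linked Zfx at 1.94 ± 0.0990 against 4 ± 0.877 (SD, n = 2 each). None of the 46 passed, over all genes or adjusted over the list alone. Camera called the list lower (adjusted p = 0.00881; adjusted p = 0.990 with an estimated correlation, and 0.209 without wild-type replicate 1).

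Markers of the stages before pachytene, from preleptotene to zygotene, were also lower as a list. The median log2 difference was -0.26 over 22 measured members, of which 11 were lower and 2 higher in both heterozygote libraries. The median was -0.09 without wild-type replicate 1. The 2 were Meiob, a meiotic single-strand DNA binding protein (15.4 ± 0.417 against 9.76 ± 0.926 FPKM), and Spo11, which makes the double-strand breaks of meiosis (85.1 ± 9.76 against 60.4 ± 8.16 FPKM). Ccdc36 was at 8.60 ± 0.643 against 14.7 ± 2.72 FPKM and Prss50 at 4.06 ± 0.283 against 7.62 ± 2.95 FPKM (SD, n = 2 each). Camera called the list (adjusted p = 0.0237), but not with an estimated correlation (adjusted p = 0.990), without wild-type replicate 1 (adjusted p = 0.0589) or without heterozygote replicate 1 (adjusted p = 0.268), and 0 of 22 members passed singly, over all genes or adjusted over the list alone. The list shares 17 measured genes with that of the synaptonemal complex, cohesin and recombination, which had a median log2 difference of 0.0036 over 46 members (adjusted p = 0.966; -0.16 to 0.12 without 1 library), with a mean and a camera direction below 0.

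Markers of round and elongating spermatids, the cell types that follow meiosis, were higher, with a median log2 difference of 0.36 over 36 members. The median was 0.97 without wild-type replicate 1, 0.59 without heterozygote replicate 2, 0.12 without heterozygote replicate 1 and -0.19, the other direction, without wild-type replicate 2. The protamine genes Prm1 and Prm2 were at 467.6 ± 77.9 and 585.4 ± 38.5 FPKM in the heterozygote and at 180.7 ± 94.8 and 234.0 ± 137 in the wild type. The transition protein genes Tnp1 and Tnp2 were at 344.0 ± 27.0 and 472.2 ± 82.6 against 147.3 ± 86.2 and 176.0 ± 107 FPKM (SD, n = 2 each). The mean log2 level of the list was 5.52 and 4.42 in wild-type replicates 1 and 2 and 5.65 and 5.11 in heterozygote replicates 1 and 2, so the difference between the wild-type libraries exceeded that between the genotypes. Camera called the list (adjusted p = 0.0115), but not with an estimated correlation (adjusted p = 0.990), without wild-type replicate 2 (adjusted p = 0.702) or without heterozygote replicate 1 (adjusted p = 0.298), and 0 members passed singly, over all genes or adjusted over the list alone. Genes of chromatin condensation in spermatids, 12 of which are in both lists, had a median log2 difference of 0.21 over 28 members (adjusted p = 0.261). Camera called them higher without wild-type replicate 1 (adjusted p = 0.000403, median 0.60), while the median was -0.03 without wild-type replicate 2, 0.12 without heterozygote replicate 1 and 0.45 without heterozygote replicate 2.

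X-linked genes, which are silenced in pachytene spermatocytes, were lower as a group, with a median log2 difference of -0.20 over 484 measured genes. The median was -0.47 without wild-type replicate 2, -0.50 without heterozygote replicate 1 and 0.06 and 0.15 without wild-type replicate 1 and heterozygote replicate 2. A lower mean log2 level in the heterozygote was found for 374 of them, while 437 overlapped between the genotypes. Their median FPKM was 2.48 and 1.35 in wild-type replicates 1 and 2 and 2.04 and 1.03 in heterozygote replicates 1 and 2. Sertoli cell markers were likewise lower in replicate 2 of each genotype, with a mean log2 level of 4.39 and 3.84 in the wild type and 4.46 and 3.14 in the heterozygote. Camera called the X-linked genes (adjusted p = 0.0045; adjusted p = 0.990 with an estimated correlation), and the direction turned without wild-type replicate 1 (adjusted p = 0.957) and without heterozygote replicate 2 (adjusted p = 0.146). The call was also lost with the Sertoli markers as a covariate (adjusted p = 0.637), and 0 of 484 genes passed over all genes or adjusted over the list alone. Y-linked genes had a median log2 difference of -0.21 over 123 members (-0.63 to 0.16 without 1 library) and were not called (adjusted p = 0.156), but were called lower without wild-type replicate 2 (adjusted p = 6.44e-05) and without heterozygote replicate 1 (adjusted p = 0.000505), and turned without either of the other libraries. Adjusted over the list alone, 1 of them rose, the multicopy Sly, whose values are uncertain.

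**Figure D2:**
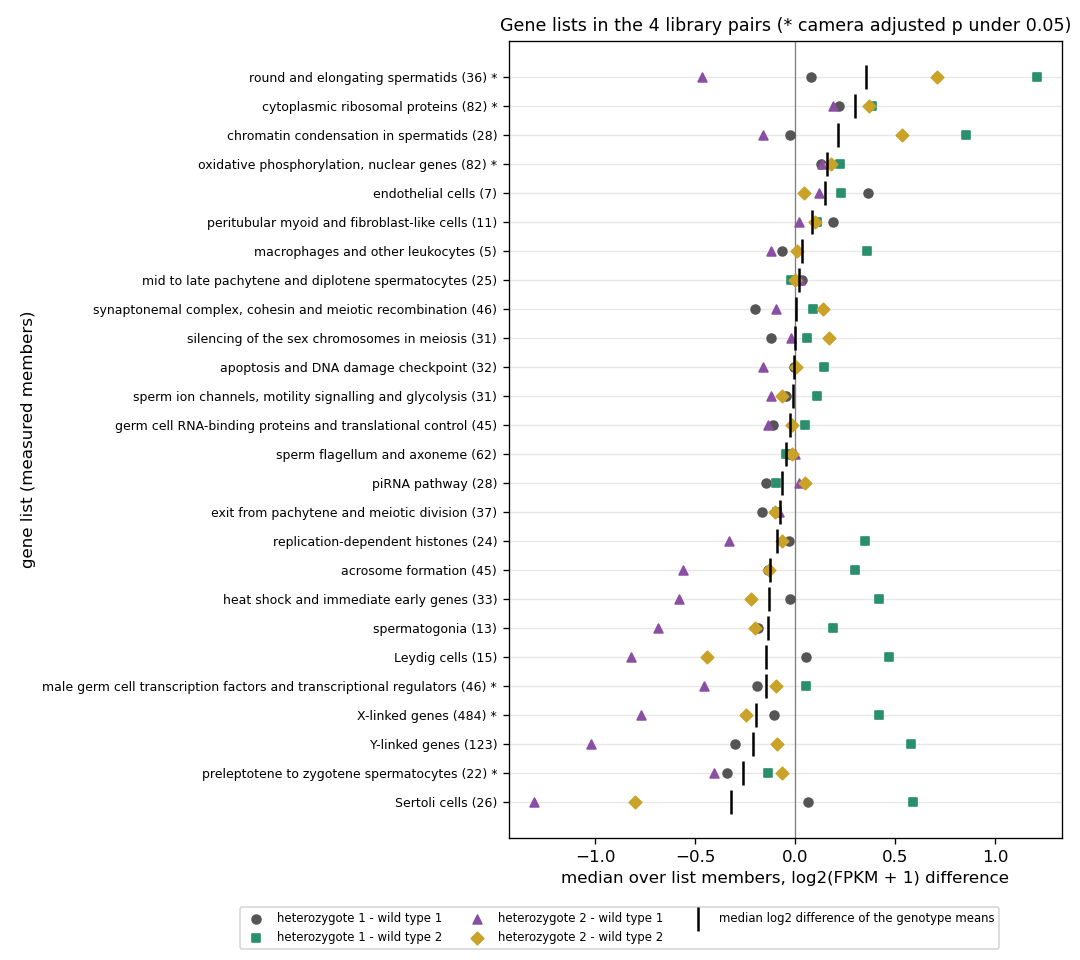
Median over the measured members of each gene list of the log2(FPKM + 1) difference in each of the 4 pairings of a heterozygote with a wild-type library (points) and of the genotype means (black bars), with the lists called by camera marked by an asterisk. Ribosomal protein genes lie above 0 in every pairing, from 0.19 to 0.38, while spermatid markers run from -0.47 to 1.21 and X-linked genes from -0.77 to 0.42.

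In the other lists fixed for this tissue, single genes passed when adjusted over the list alone, by limma-trend, while in the same fit, with genotype as the only term, all 4 libraries and the filter at 0.5 FPKM, no gene passed over all genes and camera called none of these lists. In the list of exit from pachytene and meiotic division (median log2 difference -0.08, and -0.14 to -0.09 without 1 library; 37 members, adjusted p = 0.0914), the cyclin gene Ccna1, needed for the first meiotic division, fell from 151.5 ± 12.4 to 89.1 ± 10.04 FPKM (adjusted p = 0.0419). Camera called this list lower without wild-type replicate 1 (adjusted p = 0.0164) and without heterozygote replicate 2 (adjusted p = 0.00771), and, with all 4 libraries, without a filter (0.0297), with quantile normalization (0.0437) and with the Sertoli covariate (0.0252). With fry this list had the lowest adjusted p of any list tested, 0.0541 (unadjusted p = 0.00208), and was not called. Its median was below 0 in all 4 pairings of a heterozygote with a wild-type library (-0.17 to -0.08). Aurkb, a kinase of the chromosomal passenger complex, was at 8.34 ± 0.714 against 18.6 ± 4.62 FPKM without passing. In the list of acrosome formation (median -0.13, 45 members, adjusted p = 0.318, and 0.0458 with quantile normalization and 0.00728 with the spermatid covariate), the direction of the median depended on the library left out. It was 0.11 without wild-type replicate 1, 0.10 without heterozygote replicate 2, -0.28 without wild-type replicate 2 and -0.32 without heterozygote replicate 1. Adam3, a sperm surface protein needed for migration in the oviduct, fell in that list from 502.0 ± 53.9 to 297.8 ± 4.15 FPKM (adjusted p = 0.0240). Prss21 also fell from 93.3 ± 11.0 to 46.8 ± 10.7 FPKM and Izumo4 from 161.5 ± 11.7 to 118.6 ± 1.70 FPKM (adjusted p = 0.0457 each). In the list of sperm ion channels, motility signalling and glycolysis (median -0.01, and -0.10 to 0.08 without 1 library; 31 members, adjusted p = 0.966), the glycolytic gene Pgam2 rose from 795.2 ± 41.0 to 1224.7 ± 88.7 FPKM (adjusted p = 0.0249). In the list of mid to late pachytene and diplotene markers (median 0.02, and -0.01 to 0.05 without 1 library; 25 members, adjusted p = 0.966, with a camera direction below 0), Adam3, Ccna1 and Tbpl1 fell and Ybx2, which stores germ cell mRNA, rose from 2079 ± 4.26 to 2607 ± 17.6 FPKM (adjusted p = 0.0279; SD, n = 2 each).

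In the same fit camera called none of the other germ cell lists, and no member of them passed. Their medians changed sign with the library left out. The median log2 difference was -0.06 for the piRNA pathway (28 members, adjusted p = 0.814, and 0.0383 without heterozygote replicate 2; medians without 1 library -0.08 to 0.03), -0.03 for germ cell RNA-binding proteins (45 members, adjusted p = 0.610; -0.13 to 0.02) and -0.04 for the flagellum and axoneme (62 members, adjusted p = 0.907; -0.04 to 0.006). It was -0.0031 for factors that silence the sex chromosomes (31 members, adjusted p = 0.940; -0.09 to 0.10) and -0.0071 for apoptosis and the DNA damage checkpoint (32 members, adjusted p = 0.966; -0.15 to 0.07), and for both of these the camera direction was above 0. It was -0.13 for heat shock and immediate early genes (33 members, adjusted p = 0.109, and 0.0127 and 5.97e-05 without wild-type replicate 2 and heterozygote replicate 1, 0.0422 with the GC correction and 0.000642 with the spermatid covariate). The heat shock median turned to 0.23 without heterozygote replicate 2 (adjusted p = 0.440) and to 0.04 without wild-type replicate 1 (adjusted p = 0.826), and was -0.33 and -0.49 without the other 2. It was -0.09 for replication-dependent histones (24 members, adjusted p = 0.966; -0.15 to 0.16).

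Markers of other testis cells were measured to follow RNA from cells other than pachytene spermatocytes. Sertoli markers had a median log2 difference of -0.32 over 26 members (adjusted p = 0.109), and all 26 overlapped between the genotypes. Clu, an abundant one, was at 371.1 and 247.2 FPKM in the wild type and at 342.2 and 125.3 FPKM in the heterozygote. The list was called lower without heterozygote replicate 1 (median -1.04, adjusted p = 1.32e-11). It turned to higher in the heterozygote (median 0.33, adjusted p = 0.00451) when heterozygote replicate 2 was left out. The median was -0.13 and -0.61 without wild-type replicates 1 and 2. Leydig markers had a median of -0.15 (15 members, adjusted p = 0.319). They were at -0.55 without heterozygote replicate 1 (adjusted p = 0.000167), turned to 0.21 without heterozygote replicate 2 (adjusted p = 0.173) and were at -0.01 and -0.35 without wild-type replicates 1 and 2. Spermatogonial markers had a median of -0.13 (13 members, adjusted p = 0.450), which turned to 0.17 without wild-type replicate 1 and was -0.43 without wild-type replicate 2. It was -0.53 and -0.02 without heterozygote replicates 1 and 2. Peritubular myoid markers had a median of 0.09 (11 members, adjusted p = 0.611; -0.04 to 0.15 without 1 library). Macrophage and leukocyte markers had a median of 0.03 (5 members, adjusted p = 0.966, mean below 0; -0.06 to 0.15). Endothelial markers had a median of 0.15 over 7 members (adjusted p = 0.966, mean below 0; 0.12 to 0.31), of which Sox17 fell when adjusted over the list alone (limma-trend, adjusted p = 0.00701). Of the erythroid markers 3 were measured, with a median of -0.44, and of the mitochondrially encoded genes 0 were listed, so neither list was tested.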

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

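The scalings, the quantile normalization, the stricter filter, the robust and trend-free fits, the marker covariates, the GC and length corrections, the gap count and the X-linked set without uncharacterised symbols were chosen after seeing the data. The planned edgeR normalizations, the count filters, the DESeq2, voom and robust edgeR fits were not run, because they need counts, and leaving out mitochondrially encoded genes moved nothing, because none was listed. The depth of the libraries is unknown, so the limit it sets on low genes cannot be given.

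The count of genes passing stayed at 0 with a pseudocount of 0.1, without a filter, with the stricter filter, at a threshold of 0.01 or 0.1, with sum or upper-quartile scaling, and with the robust and trend-free fits. It was also 0 without each library in turn, but those fits have 1 residual degree of freedom and a genotype of 1 library, so that 0 says little. It was 65 with median-ratio scaling, 119 with quantile normalization, 57 with the GC correction, 63 with the length correction, 382 with the spermatid covariate and 54 with the Sertoli covariate, and the cause was not tested. Of the 85 genes at least 2-fold apart, these calls held 62, 61, 54, 61, 85 and 46. The covariate fits leave 1 residual degree of freedom, and their false calls were not simulated. The gap count was 195 with the smaller pseudocount, 81 with the GC and 77 with the length correction and 66 to 86 with the scalings, and 115 to 190 without 1 library (190 without wild-type replicate 1, 99 higher and 91 lower, 141 without wild-type replicate 2, 160 without heterozygote replicate 1, 115 without heterozygote replicate 2), where fewer library pairs must differ. Tcfl5 was lower under all of these settings and passed under none of them, with log2 differences from -0.82 to -0.37 without 1 library. The 24 named genes kept their direction under every setting run, which leaving out a library could not change, since they were named for a gap between the genotypes.

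The labels give both genotypes replicate numbers 1 and 2 without saying what a number shares. The deviations of same-numbered libraries from their genotype means correlated at 0.529 across genes. With the replicate number as a block, 1213 genes passed (650 higher, 563 lower), among them all 24 named genes, Tcfl5 passed (-0.59, adjusted p = 0.00339), and 11 lists were called. That fit leaves 1 residual degree of freedom. In 10 simulated draws of 13333 genes it made 5 to 73 false calls beside 200 changed genes, up to 26.7% of its calls, so the adjusted p under the block understates the false calls.

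With an estimated correlation 0 lists were called (adjusted p 0.990 for each of the 6). With fry 0 were called, the lowest adjusted p being 0.0541 for exit from pachytene. The 6 had 0.721 (ribosomal proteins, oxidative phosphorylation) and 0.977 (transcription factors, preleptotene to zygotene markers, spermatids, X-linked genes). With the spermatid covariate 11 lists were called. Loss of the spermatid list (0.616) was fixed in advance, the covariate being the mean of its markers. X-linked genes were lost with the Sertoli covariate (0.637) and oxidative phosphorylation with the length correction (0.0949). The cause was not tested. Without 1 library, the adjusted p ran from 0.000102 to 0.209 for transcription factors (lost without wild-type replicate 1), from 0.00191 to 0.268 for preleptotene to zygotene markers (lost without wild-type or heterozygote replicate 1, at 0.0589 and 0.268), from 8.00e-13 to 0.702 for spermatids (lost without wild-type replicate 2 or heterozygote replicate 1, at 0.702 and 0.298) and from 1.22e-13 to 0.957 for X-linked genes (turned without wild-type replicate 1 or heterozygote replicate 2, at 0.957 and 0.146). Ribosomal proteins and oxidative phosphorylation kept their calls without each library.

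Some lists that were not called changed sign, with these adjusted p. With fry these were the synaptonemal complex and endothelial lists (0.977). Without a filter they were sperm ion channels (0.978), apoptosis and macrophages (0.892) and myoid cells (0.918). With the block it was the pachytene list (0.869), with sum scaling the histones (0.981), and with median-ratio scaling the pachytene and endothelial lists (0.929). With quantile normalization it was sex chromosome silencing (0.998), which also turned with the Sertoli covariate (0.924). With the spermatid covariate the piRNA, flagellum, apoptosis and macrophage lists (0.933) and the pachytene list (0.580) turned. With the GC correction the synaptonemal complex, pachytene and endothelial lists turned (0.963), and with the length correction the endothelial (0.947) and macrophage lists (0.954).

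Without 1 library, further uncalled lists turned at least once. Their adjusted p ran from 0.183 to 0.730 for the synaptonemal complex, 0.0383 to 0.791 for piRNA, 0.283 to 0.678 for the flagellum, 0.776 to 0.856 for sperm ion channels, 0.276 to 0.783 for sex chromosome silencing, 0.576 to 0.947 for apoptosis, 5.97e-05 to 0.826 for heat shock genes, 0.633 to 0.991 for histones and 0.520 to 0.642 for the pachytene list. They ran from 0.466 to 0.758 for endothelial cells, 0.466 to 0.991 for macrophages, 1.32e-11 to 0.717 for Sertoli cells, 0.000167 to 0.758 for Leydig cells and 6.44e-05 to 0.972 for Y-linked genes. Direction here is that of camera; the medians of the acrosome list also turned without wild-type replicate 1 (0.11) and heterozygote replicate 2 (0.10), of spermatogonial markers without wild-type replicate 1 (0.17), of RNA-binding proteins (0.02) and myoid cells (-0.04) without it too, and of chromatin condensation without wild-type replicate 2 (-0.03). Sertoli markers were called lower without heterozygote replicate 1 (1.32e-11) and higher without heterozygote replicate 2 (0.00451).

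Lists not called with all libraries in the planned fit gained a call, in their own direction, under other settings. Y-linked genes were called lower with the block (0.0103), median-ratio scaling (0.0321), the stricter filter (0.0340), the length correction (0.00078) and the spermatid covariate (1.82e-06). Chromatin condensation was called higher with the block (0.00922), median-ratio scaling (0.00737), the GC (0.0199) and length corrections (0.0192) and the Sertoli covariate (0.0417), and exit from pachytene lower without a filter (0.0297), with quantile normalization (0.0437) and with the Sertoli covariate (0.0252). Sertoli markers were called lower with the block (0.0014), median-ratio scaling (0.00976), quantile normalization (0.0458), the spermatid covariate (0.000835) and the GC (0.0141) and length corrections (0.00626). Heat shock genes were called lower with the block (0.0222), the spermatid covariate (0.000642) and the GC correction (0.0422), the acrosome list with the block (0.0284), quantile normalization (0.0458) and the spermatid covariate (0.00728), and Leydig (0.0410) and spermatogonial markers (0.0470) with the spermatid covariate. The cause was not tested.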

Other observations

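The tests with outcomes unseen when their expected values were written down are those of matched transcript length and of scaling for the ribosomal protein genes, of GC content for the replicate numbers and of neighbouring genes; the other tests were chosen after the result was seen.

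Beyond the named genes, the 62 genes at least 2-fold lower in every library pair held further genes, chosen for naming after their values were seen. The growth factor genes Pgf (0.975 ± 0.346 against 6.51 ± 0.134 FPKM), Tgfa (1.81 ± 0.438 against 6.79 ± 2.04 FPKM) and Fgf11 (0.745 ± 0.0212 against 2.90 ± 0.0636 FPKM) were lower in the heterozygote. So were the receptor genes Flt3 (0.775 ± 0.0495 against 3.09 ± 0.438 FPKM), Epha7 (0.810 ± 0.113 against 3.39 ± 0.0283 FPKM) and Ltbr (3.13 ± 0.346 against 10.8 ± 0.615 FPKM), and the kinase genes Pik3cd (7.79 ± 0.177 against 21.02 ± 2.04 FPKM) and Rps6ka4 (4.03 ± 0.530 against 11.2 ± 0.962 FPKM). The transcription factor genes Six2 (0.620 ± 0.226 against 3.76 ± 0.495 FPKM), Hey1 (1.03 ± 0.0283 against 3.45 ± 0.0424 FPKM) and Snai2 (0.595 ± 0.304 against 3.08 ± 0.488 FPKM; SD, n = 2 each) were lower too. None of these genes passed limma-trend after adjustment.

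The 85 genes at least 2-fold apart between the genotypes were weighed against RNA of spermatids and Sertoli cells, GC content and scaling. More RNA of spermatids as a whole in the heterozygote libraries would raise spermatid markers in each library pair. Between heterozygote replicate 2 and wild-type replicate 1, however, the median of 36 markers was -0.47 (quartiles -0.85 and 0.11). Of the 36, 10 were higher in both heterozygote libraries than in both wild-type libraries, 0 were lower and 26 overlapped. The list mixes round and elongating spermatids, so its median cannot decide for RNA of only some spermatid stages. Less Sertoli cell RNA would lower Sertoli markers in each pair, but between heterozygote replicate 1 and wild-type replicate 2 the median of 26 was 0.59 (quartiles 0.47 and 0.78). After correction for GC content 76 of the 85 genes kept the gap, and under the scaling that kept fewest 65 did, which argues against these as the whole cause. RNA of other cells or stages was not weighed for these genes and stays open. Preleptotene to zygotene markers were lower in each library pair (medians of -0.06 to -0.41). Peritubular myoid and endothelial markers, close to the floor, were higher in each (0.02 to 0.19 and 0.04 to 0.36). An effect of the genotype stays open as a hypothesis, and so does chance. Only 3 splits of the libraries exist, too few for a share under 0.05. The real split, 1 of the 3, gave 85 genes and the highest of the other splits 25.

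The rise of ribosomal protein genes as a group was set against transcript length, other cells and scaling. Their transcripts are short (median 800 bases, against 2949 for the genes tested), and 10000 random lists matched on length and level had a median log2 difference of 0.12, so part of the 0.30 is shared by short, abundant transcripts. None of those lists reached it (0% of them, highest 0.25), which argues against length as the whole cause. In the pair where Sertoli and Leydig markers were lower by -1.31 and -0.82, heterozygote replicate 2 against wild-type replicate 1, the ribosomal protein genes had a median of 0.19 (quartiles 0.09 and 0.34), against RNA of Sertoli or Leydig cells as the source, and under 4 scalings their median exceeded that of all genes by at least 0.22. RNA of other somatic cells stays open, and so does RNA of other germ cell stages, which was not weighed for these genes. Preleptotene to zygotene markers were lower in each library pair (medians of -0.06 to -0.41), while spermatid medians ran from -0.47 to 1.21. Peritubular myoid, endothelial and leukocyte markers had medians of 0.086, 0.15 and 0.033 between the genotypes, the first 2 above 0 in all 4 library pairs, and with median levels of 1.63, 0.75 and 2.92 FPKM they are too close to the floor to decide. A response to the Tcfl5 dose may account for the rest, but these genes vary together. With an estimated correlation camera did not call the list (adjusted p = 0.990, as for every set tested, and unadjusted p = 0.222).

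The libraries also differed by replicate number within each genotype. The first principal component held 54.8% of the variance. It placed the libraries in the order wild-type replicate 1, heterozygote replicate 1, wild-type replicate 2 and heterozygote replicate 2. The second held 33.4% and separated the genotypes, with wild-type replicates 1 and 2 at -4.14 and -25.4 and heterozygote replicates 1 and 2 at 21.3 and 8.18. By limma-trend, a split by replicate number gave 2082 genes at an unadjusted p under 0.05, against 1759 for the genotypes. Markers of spermatids and of Sertoli cells were lower in replicate 2 in both genotypes, the smallest of the 4 drops being a median of -0.43, consistent with more RNA of those cells in the replicate 1 libraries; 12 spermatid markers are also in the list of chromatin condensation and 1 Sertoli marker in that of Leydig cells. A trend on GC content is argued against as the whole cause, since the spermatid median between replicate numbers was -0.78 before and -0.66 after the correction (quartiles -0.85 and -0.55). No biological explanation was tested for this pattern, because the design names no group that follows the replicate numbers, and shared handling stays open.

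Art1 and Art5 lie next to each other, and whether differing genes share neighbourhoods was tested as a hypothesis. Of 75 genes at least 2-fold apart that have a position on a primary autosome, 2 had another of the same direction within 50 kb, these being Art1 and Art5, and 16.9% of 10000 random sets matched on level had as many. The only neighbours counted were the pair that raised the question, so the count is no separate evidence. The test leaves open whether the pair may share a local change.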
